A study of Canis lupus familiaris with 14 samples.

How the data were processed

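Whole blood RNA of 14 dogs was sequenced, 7 dogs with lymphoma and 7 control dogs with a disease other than lymphoma. Per the labels' protocols, RNA was extracted from blood with Trizol, chloroform and isopropanol, and libraries were prepared with standard Illumina protocols in both groups. The labels do not say whether ribosomal RNA was depleted or polyadenylated RNA selected. The deposited file is 1 table of raw counts per gene, made by the authors with featureCounts 2.0.1, per the file headers, on read pairs assigned to exons and summed by gene. The header's command sets no strand option and no option for reads that map to several places or overlap several genes. Reads of antisense and overlapping partners therefore could not be told apart by strand. Per the submitters' processing notes, HISAT2 2.2.1, Subread 2.0.1, featureCounts and DESeq2 were used with the CanFam3.1 assembly, and the header names the gene annotation of Ensembl release 103.

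The table lists 30951 genes by Ensembl identifier with their positions in CanFam3.1 and no symbols. The reference gene table used here, of the assembly UU_Cfam_GSD_1.0, matched 0 of these identifiers. The files do not pair identifiers with names, so genes are described by position, exon structure and chromosome, and at most 2 identifiers are printed for each direction. Marker, pathway and cell type lists had been fixed before the data were examined, 39 in all. None of the 39 could be matched, so no gene list was tested.

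Total counts ranged from 9845059 to 14831589 in the lymphoma libraries and from 13522628 to 21610927 in the non-lymphoma libraries. The groups were compared with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM factors, genes kept by filterByExpr, group as the only term and Benjamini-Hochberg adjustment at 0.05. After the filter 12836 genes were tested, and the biological coefficient of variation was 41.5%. Standard errors of log2 fold changes were obtained as the absolute fold change divided by the square root of F. Log2 CPM values were computed with a prior count of 2. On simulated counts with 200 changed genes, 12630 genes were tested. The procedure recovered 43 of 100 genes changed by a log2 fold of 1 and 71 of 94 changed by 2, with 5 false calls.

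Single values, chromosome means and gene classes were compared with two-sided exact permutation tests over the 3432 assignments of 7 of the 14 libraries to lymphoma, for which the smallest p is 0.000583. Chromosomes with at least 5 tested genes were scored by the mean log2 CPM of their tested genes, and p-values were adjusted over 40 chromosomes, the mitochondrial one included. Separation of the groups was measured by a pseudo-F on Euclidean distances over the 500 most variable tested genes, with a one-sided exact permutation test. Windows of 10 consecutive tested genes, 12377 in all, were scanned for regional differences. The family-wise p of a window came from the largest window difference in each of the 3432 assignments, and overlapping windows under 0.05 in one direction were merged. The window scan, the gene classes by exon structure and the shares of counts were chosen after the data were seen. On simulated values a shifted chromosome and a shifted window were each recovered, with 1 other chromosome called and 0 other windows. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used for these steps.

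The rule for single genes was fixed before the data were examined. It took genes with an adjusted p under 0.05, an average log2 CPM of at least 1, a symbol, and at least 6 of 7 lymphoma libraries on the fold change's side of the non-lymphoma median, and kept the 12 largest rises and the 12 largest falls. The condition on symbols was dropped because no identifier had one. The rule also took the 4 members with the lowest p of each chromosome that passed and of fixed marker lists. The marker lists could not be matched, and the chromosome members are summarised.

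The sample numbers in the labels take 5 digits in all 7 non-lymphoma and in 2 lymphoma libraries, and another form in 5 lymphoma libraries. The labels do not state whether this form marks a batch, and values within the 5-digit libraries are given as within-batch values in case it does. The remaining form holds lymphoma libraries alone and gives no such value. No 2 libraries were near-identical, with a smallest chi-square per degree of freedom of 59.2 between any pair. Alternatives covered normalization with RLE, upper-quartile factors and another TMM version, filters, dispersion, covariates, DESeq2 1.42.0, limma 3.58.1, sva 3.50.0, thresholds and subsets of libraries.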

Results

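The transcriptome of whole blood was measured by RNA sequencing in 7 dogs with lymphoma, a cancer of lymphocytes, and in 7 control dogs with a disease other than lymphoma. The labels describe each library as its own sample and say no more of the animals, so p-values measure the spread between these libraries. The mean total count was 11728112 ± 1929960 (SD, n = 7) in lymphoma and 16647055 ± 2477439 (SD, n = 7) in non-lymphoma blood. Totals were lower in lymphoma by an exact permutation test (p = 0.00117, adjusted p = 0.00293 over 15 library measures). Genes with at least 1 count numbered 16657 ± 1079 (SD, n = 7) in lymphoma and 21341 ± 2610 (SD, n = 7) in non-lymphoma libraries. After all libraries were thinned to the smallest total, the numbers were 16484 ± 989 and 19875 ± 2144 (SD, n = 7 each), and the difference held in the exact permutation test (p = 0.00408, adjusted p = 0.00765). Thinning matched totals only. The 10 most abundant genes took 38.9 ± 7.46% of counts in lymphoma and 29 ± 8.23% in non-lymphoma libraries (SD, n = 7 each; exact permutation p = 0.0297, adjusted p = 0.0495). Fewer counts were thus left for other genes in lymphoma. Within the libraries with 5-digit sample numbers, 2 of them lymphoma, the thinned number was lower by 2826 in lymphoma (exact permutation p = 0.139).

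The mitochondrial chromosome took 21 ± 3.2% of counts in lymphoma and 19 ± 7.69% in non-lymphoma blood (SD, n = 7 each), a difference within the spread (exact permutation p = 0.343). A single-exon mitochondrial gene at positions 1091 to 2670 alone took 17.2 ± 2.66% and 14.7 ± 6.06% (SD, n = 7 each). The next most abundant genes lay on chromosome 6 at 40235272 to 40329010, with 4.53 ± 3.21% and 6.28 ± 3.06% of counts, and on chromosome 21 at 28178124 to 28206005, with 8.31 ± 4.76% and 3.09 ± 1.34% (SD, n = 7 each). The chromosome 21 gene had a log2 fold change of 1.82 (SE 0.55, edgeR adjusted p = 0.0347), a call lost when lymphoma replicate 2 or 7 or non-lymphoma replicate 1, 3, 5, 6 or 7 was left out (log2 fold change of at least 1.45, edgeR adjusted p up to 0.0789). The chromosome 6 gene had a log2 fold change of -0.18 (SE 0.53, edgeR adjusted p = 0.839).

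The comparison of lymphoma with non-lymphoma blood asked which transcripts differ in dogs with lymphoma. Of 12836 tested genes, 2132 differed by edgeR's quasi-likelihood test, 1182 higher and 950 lower in lymphoma. The balance of the calls turned to 985 higher and 1181 lower with upper-quartile factors, and to 869 and 1133 without a filter on low counts. The median fold among called genes was 2.15 for those higher and 1.91 for those lower, and 678 higher and 411 lower genes changed by a log2 fold of at least 1. Among the 12 genes with the largest rise, 4 lay on unplaced scaffolds, 5 were single-exon genes of 200 to under 400 bases, and 3 were placed genes with several exons, with log2 fold changes from 4.16 to 10.07. Among the 12 with the largest fall, 10 were placed genes with several exons, 2 of them on chromosome 8 and 2 on chromosome 26, with log2 fold changes from -4.24 to -2.66. Of the 12 rising genes 6 overlapped another annotated gene, as did 6 of the 12 falling genes, and their counts are uncertain to that extent. Within the 5-digit libraries 104 genes were called, 82 higher and 22 lower, 87 of them shared with the 2132. With the share of counts on called scaffold genes as a covariate, chosen after seeing the data, 1 gene was called, in a fit where that share separated the groups completely.

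ENSCAFG00000036997, a 2-exon gene on an unplaced scaffold, had 272 to 3107 counts in lymphoma and 0 to 4 in non-lymphoma libraries, with a log2 fold change of 10.07 (SE 0.95, edgeR adjusted p = 3.56e-05; 9.34 without lymphoma replicate 7). ENSCAFG00000038302, a 2-exon gene on another scaffold, had 19 to 185 counts against 0 to 2, with a sum of 4 counts over the non-lymphoma libraries. Its fitted log2 fold change of 7.39 (SE 0.88, edgeR adjusted p = 0.000271; 8.02 without non-lymphoma replicate 2) rests on that small sum. ENSCAFG00000045680, a 2-exon gene of 315 exonic bases at 73586711 to 73595785 of chromosome 8, fell by 4.24 on the log2 scale (SE 0.82, edgeR adjusted p = 0.0051; log2 fold change -5.51 without lymphoma replicate 5), from 22 to 513 counts in non-lymphoma to 0 to 28 in lymphoma libraries. ENSCAFG00000048588, a 5-exon gene at 16473001 to 16486109 of chromosome 1, fell by 3.78 (SE 0.53, edgeR adjusted p = 0.00088), from 37 to 142 counts to 0 to 9. All 4 genes had every lymphoma library on the same side of the non-lymphoma median. Within the 5-digit libraries the rising genes were called and the falling ones were not. There ENSCAFG00000045680 had a log2 fold change of -3.14 (edgeR adjusted p = 0.2) and ENSCAFG00000048588 of -4.51 (edgeR adjusted p = 0.0808). ENSCAFG00000048588 overlaps no other annotated gene, and the other 3 do.

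Libraries of the 2 groups stood apart. The pseudo-F over the 500 most variable genes was 5.94 (one-sided exact permutation p = 0.000583, the smallest the splits can give). The mean Euclidean distance was 62.3 between groups, 52.9 among lymphoma libraries and 41.1 among non-lymphoma libraries. Spread was compared by permuting labels without centring each group, so its p may also reflect the distance between the groups. The larger spread within lymphoma, by 11.8, passed this two-sided exact permutation test (p = 0.0402). It no longer passed over all tested genes (difference 19.6, exact permutation p = 0.186), with 1 minus Spearman correlation as the distance (0.00405, exact permutation p = 0.937), or when any 1 of the 7 lymphoma libraries was left out (9.13 without replicate 2 to 13.7 without replicate 3, exact permutation p from 0.0507 to 0.14). The same held without non-lymphoma replicate 4 (10.9, exact permutation p = 0.06), 5 (11, exact p = 0.0594) or 6 (10.1, exact p = 0.0723). The first principal component held 30% of the variance and the second 15.8%.

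**Figure D1:**
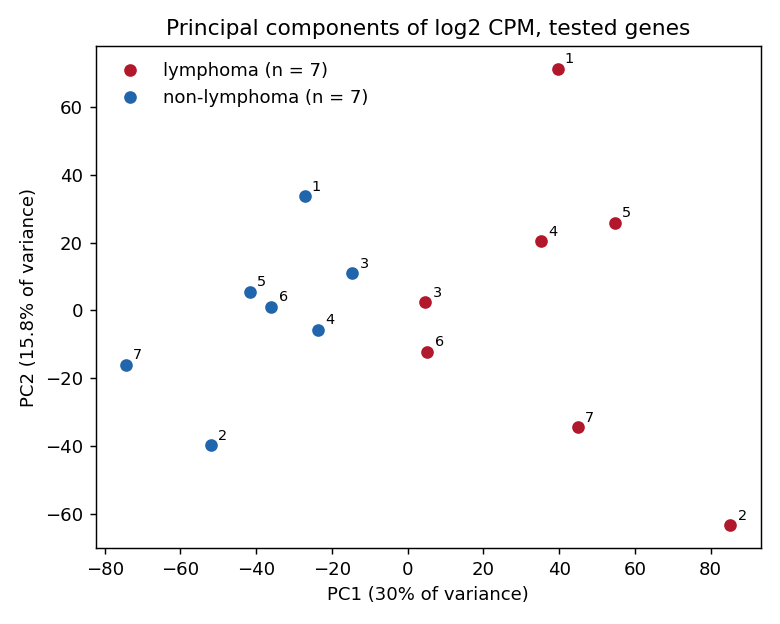
Principal components of log2 CPM over the tested genes, with PC1 (30% of variance) on the horizontal and PC2 (15.8%) on the vertical axis, each point a library numbered by replicate. The 7 lymphoma libraries lie at PC1 of 4.7 or more and the 7 non-lymphoma libraries at -14.6 or less.

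Of 99 tested genes on unplaced scaffolds, 5 were higher and 8 lower in lymphoma. The 5 higher genes together took 0.927 ± 0.561% of counts in lymphoma and 0.0083 ± 0.0112% in non-lymphoma libraries (SD, n = 7 each), a 224-fold difference of geometric means. Without non-lymphoma replicate 7 the non-lymphoma share was 0.00535 ± 0.00877% (SD, n = 6). No p is given for this share, since its genes were chosen as called higher in the same libraries. The lowest lymphoma share was 10.8 times the highest non-lymphoma share. Within the 5-digit libraries, which were among those used to choose the genes, the fold was 198. Most of the share came from a single-exon gene of 1869 bases with 0.886 ± 0.534% against 0.00799 ± 0.0109% (SD, n = 7 each), and a log2 fold change of 7.23 (SE 1.04, edgeR adjusted p = 0.000995; 7.83 without non-lymphoma replicate 7). The 8 lower scaffold genes had log2 fold changes from -3.21 to -0.59. Near-identical copies of scaffold and short genes were not examined, and their counts are uncertain where reads map to several copies.

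Single-exon genes of 200 to under 400 bases took 3.72 ± 2.88% of counts in lymphoma and 0.359 ± 0.154% in non-lymphoma libraries (SD, n = 7 each; exact permutation p = 0.00117). Within the 5-digit libraries the fold was 13.2 (exact permutation p = 0.0278). A group of 3 genes of 300 bases on chromosome 8, starting at 26223712, 26412228 and 26422921, made up most of it, with 3.28 ± 2.92% against 0.0529 ± 0.109% (SD, n = 7 each), and 0.0118 ± 0.00347% (SD, n = 6) without non-lymphoma replicate 2. Their log2 fold changes were 3.94, 6.72 and 5.89, with SEs of 0.67, 1.07 and 1.41 and edgeR adjusted p-values of 0.00279, 0.0019 and 0.0126. In the 5-digit libraries the gene starting at 26422921 was not called (log2 fold change 6.29, edgeR adjusted p = 0.12). The one starting at 26412228 was called there (6.82, edgeR adjusted p = 0.0251). Without non-lymphoma replicate 2 the log2 fold changes of the genes starting at 26412228 and 26422921 were 7.92 and 9.45, and without lymphoma replicate 2 that of the first of these was 6.08. These 3 genes were chosen as the short single-exon genes of chromosome 8 called higher in the same libraries, so no p is given for their share. Without the 3 genes the share was 0.439 ± 0.179% against 0.306 ± 0.071% (SD, n = 7 each; exact permutation p = 0.0839). Leaving out genes chosen as higher lowers the remaining difference in itself. As a class, these short genes did not move one way. Of 132 tested on placed chromosomes, 15 were higher and 7 lower, with a median log2 fold change of -0.03.

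**Figure D2:**
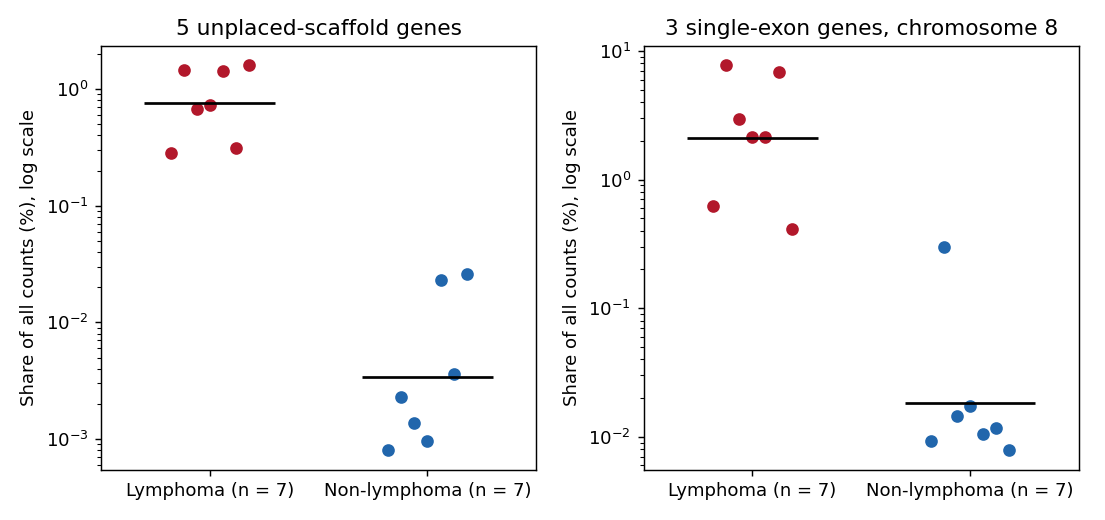
Share of all counts, in percent on a log scale, taken by the 5 called unplaced-scaffold genes (left) and the 3 single-exon genes of chromosome 8 (right) in each of 7 lymphoma and 7 non-lymphoma libraries, with lines at geometric means. The scaffold share lay between 0.281 and 1.6% in lymphoma and between 0.0008 and 0.026% in non-lymphoma libraries.

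Genes grouped by exon structure moved in different directions. Single-exon genes under 200 bases were higher in lymphoma, with 22 of 200 called higher and 2 lower and a mean difference of 0.24 in log2 CPM (exact permutation p = 0.0128, adjusted p = 0.0384 over 6 classes). Single-exon genes of 400 bases or more were lower, with 63 of 458 called lower and 20 higher and a mean difference of -0.32 (exact permutation p = 0.000583, adjusted p = 0.0035). Multi-exon genes, 11929 in number, had 1119 higher and 870 lower calls and a mean difference of -0.03 (exact permutation p = 0.309). Directions of the 2 single-exon classes were the same with RLE factors, upper-quartile factors and TMM without the 20 most abundant genes.

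A pair of regions was lower in lymphoma. On chromosome 26, 24 genes between 24630295 and 27616193 had a mean log2 CPM of 0.86 ± 1.27 in lymphoma and 2.84 ± 0.53 in non-lymphoma blood (SD, n = 7 each), with 10 genes called lower and 0 higher. With 1 library left out, 3 to 12 were called lower, with 3 when lymphoma replicate 2 was left out. The difference of the strongest window was -2.46 (family-wise exact permutation p = 0.00524), and 5 of 7 lymphoma libraries lay below every non-lymphoma library. On chromosome 8, 14 genes between 72850670 and 74243130 had a mean of 2.09 ± 0.99 against 4.19 ± 0.57 (SD, n = 7 each), with 5 called lower and 0 higher, a strongest window of -2.33 (family-wise exact permutation p = 0.00932) and 6 of 7 lymphoma libraries below every non-lymphoma library. On chromosome 8, 3 genes were called lower when lymphoma replicate 2, 3, 4 or 6 or non-lymphoma replicate 1 or 3 was left out. Within the 5-digit libraries, over the same genes, the differences were -1.34 on chromosome 26 and -1.84 on chromosome 8, given without a p since the scan chose the regions in libraries that include these. As background, chromosomes 8 and 26 of UU_Cfam_GSD_1.0 hold 87 and 39 of the 186 annotated antigen receptor V segments in the reference gene table, but positions were not compared between the assemblies.

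A region of chromosome 8 between 26223712 and 26959980 was higher in lymphoma. Its 18 genes had a mean log2 CPM of 5.34 ± 0.29 against 3.86 ± 0.34 (SD, n = 7 each), with a strongest window of 2.2 (family-wise exact permutation p = 0.0157). It holds the 3 short genes described above, and its other 15 genes had a mean of 4.07 ± 0.23 against 3.60 ± 0.26 (SD, n = 7 each), with 3 called higher and 1 lower. The lower call, at 26445647 to 26525530, was lost in 11 of 14 runs with 1 library left out, and the higher call at 26723309 to 26760984 in 8 of 14. Of the 3 higher genes, a 21-exon gene at 26251160 to 26295317 had the largest log2 fold change, 2.07 (SE 0.33, edgeR adjusted p = 0.00179), and a 32-exon gene at 26852689 to 26959980 had the highest level, with 97.4 ± 59.1 CPM against 32.6 ± 13.5 CPM (SD, n = 7 each). With 20 genes per window this region was no longer called.

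**Figure D3:**
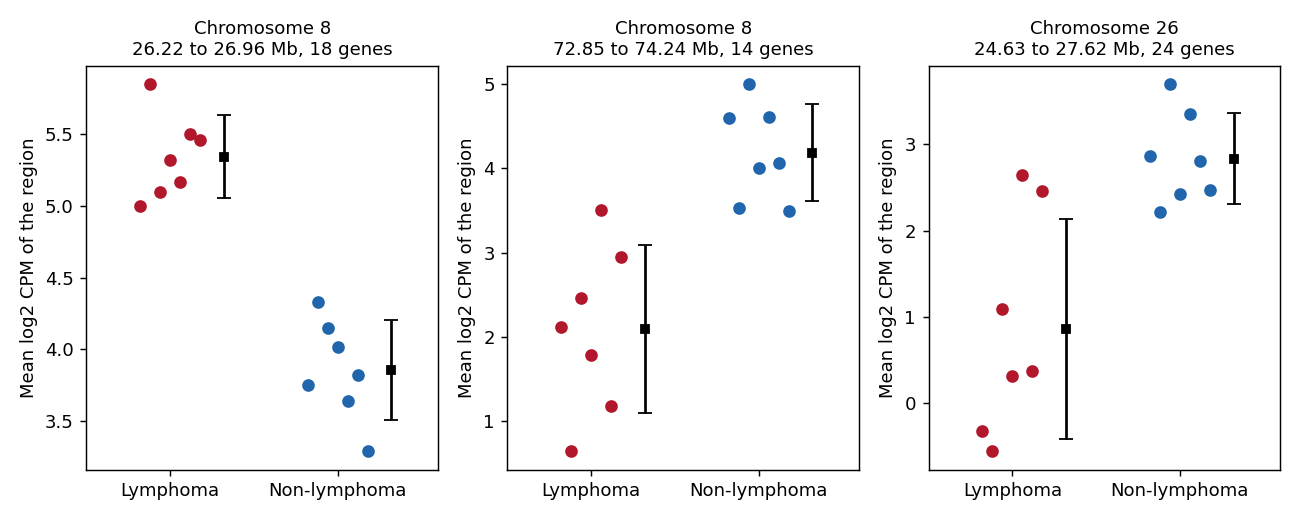
Mean log2 CPM over the genes of 3 regions in each lymphoma and non-lymphoma library, with squares and bars for the mean and SD of 7 libraries. The first region was higher in lymphoma (5.34 against 3.86), and the other 2 were lower (2.09 against 4.19, and 0.86 against 2.84).

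Means differed on 16 of 40 chromosomes, 7 higher and 9 lower in lymphoma. With camera, 7 chromosomes passed at its preset correlation and 0 with an estimated correlation (lowest adjusted p = 0.217 with an estimated correlation). The largest rises were on chromosome 36 (0.35, adjusted exact permutation p = 0.02, higher than the non-lymphoma median in 7 of 7 lymphoma libraries), chromosome 19 (0.26, adjusted exact p = 0.0117, 7 of 7), chromosome 29 (0.26, adjusted exact p = 0.00999, 7 of 7) and chromosome 32 (0.26, adjusted exact p = 0.02, 7 of 7). The largest falls were on chromosome 20 (-0.27, adjusted exact p = 0.00777, 7 of 7 libraries below), chromosome 26 (-0.25, adjusted exact p = 0.00777, 7 of 7) and chromosome 18 (-0.21, adjusted exact p = 0.00777, 7 of 7). The chromosome 26 mean, over 336 tested genes, includes the 24 genes of the region above, which differed by -1.98. It is therefore not a result apart from that region. On chromosome 20, 102 of 652 tested genes were called lower and 27 higher, and on chromosome 19, 23 of 130 were called higher and 4 lower. The 4 members with the lowest p of each of the 16 chromosomes, 64 genes in all, were picked by edgeR's p, so that all were called carries no weight. Of these genes, 46 moved in their chromosome's direction. Those of chromosome 9, where the mean difference was -0.14, all rose, with log2 fold changes from 0.99 to 2.62. Directions of all 16 chromosome means were the same with the 3 other scalings. After each library's trend of expression on local gene density was removed, 7 chromosomes passed, 5 of them among the 16, and within the 5-digit libraries 0 passed (lowest adjusted exact p = 0.111). A pass could hardly occur there, since 36 assignments give a smallest exact p of 0.0278 and 23 of 40 chromosomes would have to reach it, and all 16 kept their direction.

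**Figure D4:**
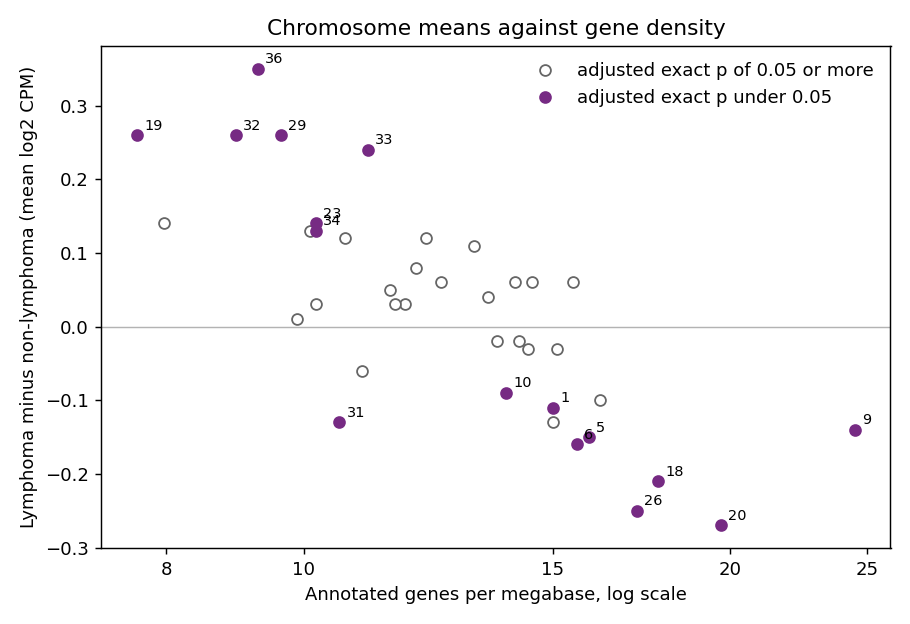
Difference in mean log2 CPM between lymphoma and non-lymphoma blood for 39 chromosomes, the mitochondrial one left out, against annotated genes per megabase on a log scale. Filled, numbered points passed an adjusted exact p of 0.05; chromosomes with fewer genes per megabase, such as 19 (7.63), lie higher, and those with more, such as 20 (19.7), lie lower.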

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

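The tests on scaffold and short-gene shares were chosen after the result was seen; those on regions and chromosomes were set out before their own values were computed, on patterns already noticed. Of 108 groups of 7 libraries examined, 10 held a library far from the rest, where chance gives about 1 in 20, or 5.4. The statistic is the gap to the nearest library divided by the range of the group. Non-lymphoma replicate 2 stood above the rest in the share of the 3 chromosome 8 short genes (0.78) and in the one starting at 26422921 (0.76). It stood below the rest in the gene of chromosome 12 starting at 19286822 (0.64) and that of chromosome 9 starting at 50770277 (0.63). Non-lymphoma replicate 7 had the lowest share of the 10 most abundant genes (0.62), and the highest level of the chromosome 1 gene starting at 60597757 (0.58). Lymphoma replicate 2 had the lowest mean of chromosomes 5 (0.62), 10 (0.69) and 26 (0.62), and lymphoma replicate 6 the lowest of chromosome 19 (0.57).

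The 5 called scaffold genes and the short chromosome 8 genes took a higher share of counts in lymphoma. After thinning to the smallest total, the 3 chromosome 8 genes and the 4 scaffold genes still tested were all called. Their log2 fold changes were then at least 3.95. The lowest lymphoma share was 10.8 times the highest non-lymphoma share for the scaffold genes and 1.38 times for the chromosome 8 genes. Thinning keeps each gene's expected share, and the genes were chosen as called higher in these libraries. These values therefore cannot decide whether depth alone is a cause. Of the 2 lymphoma libraries with 5-digit numbers, the lower in the scaffold share had 12.1 times the highest non-lymphoma share. The lower in the share of the chromosome 8 genes had 7.2 times the highest non-lymphoma share. The genes were chosen as called higher in libraries that include these 2. A batch marked by the form of the sample number is therefore not decided by these values. A difference in library preparation or RNA handling between the groups may account for the higher shares. It cannot be told apart from disease, because the labels give 1 protocol for all and no detail of preparation for single libraries. In the scaffold share 0 non-lymphoma libraries lay within the lymphoma range. That count does not decide between the 2, since the genes were chosen as called higher in lymphoma. The disease itself stays open and untested.

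The regions of chromosomes 8 and 26 were lower in lymphoma by 2 log2 units on average. A genome-wide trend with gene density is argued against as the whole cause, since the mean difference was -2.02 before and -1.92 after removing each library's trend, and a new scan of all windows after removal called both (family-wise exact permutation p = 0.0105 and 0.00699). Low counts on short 2-exon genes in general are argued against, since 76 such genes outside the regions had a median log2 fold change of -0.12. The 6 inside had a median of -2.66, which carries no weight, since the scan chose their regions as lower in these libraries. The region scores correlated within lymphoma (r = 0.87, exact permutation p = 0.0129, adjusted 0.0172; rho = 0.86, exact p = 0.0238, adjusted 0.0238; r = 0.72 without the 2 farthest libraries) and non-lymphoma (r = 0.91, exact p = 0.00456, adjusted 0.0172; rho = 0.89, exact p = 0.0123, adjusted 0.0172; r = 0.88), over 4 relations. A smaller share of transcripts from one kind of cell that uses both regions is therefore a hypothesis that the lower correlation, 0.87, is in line with, though which cell was not tested and handling differences stay open.

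Chromosome differences followed gene density, with r = -0.78 across 39 chromosomes (permutation p = 1e-05, the smallest that 100000 resamples can give; rho = -0.78, permutation p = 1e-05), and 5 of 16 calls remained in their direction once the trend was removed. The chromosomes are not independent replicates, but a trend with gene density may account for most calls, and its slope was -0.10 ± 0.12 in lymphoma and 0.10 ± 0.08 in non-lymphoma libraries (SD, n = 7 each; exact permutation p = 0.00175). What produces the trend, preparation or disease, cannot be told apart here. Copy number changes that differ between dogs are not decided, since the ratio of median chromosome SDs of lymphoma over non-lymphoma was 1.05 after the trend was removed.

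Chance is argued against for the number of genes: of 100 splits of the libraries, 1, the real one, gave as many as 2132. The highest other gave 578, with 6 of the 7 lymphoma libraries on one side, though other splits with 6 gave 0. For the 16 chromosomes, 1 of 100 splits gave as many, and the highest other gave 1. The smallest share that 100 splits can give is 1 in 100, so chance is made unlikely but not excluded for either number. The number of chromosomes also depends on the test, since camera with an estimated correlation called 0 (lowest adjusted p = 0.217).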

How the results depend on the processing

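Alternatives chosen after seeing the data were TMM without the 20 most abundant genes, thinning, leaving out gene classes or lymphoma replicates 2 and 7, the scaffold share as a covariate, camera with an estimated correlation, removal of the density trend, leave-one-out runs and the 5-digit subset for chromosomes, and those of windows and shares. The number of differentially expressed genes, 2132, stayed within 1.5 times under 25 of 32 alternatives. It was 725 with the replicate block, 104 in the 5-digit libraries, 1324 without lymphoma replicates 2 and 7, 1 with the scaffold share as covariate, 3390 with DESeq2, 1089 with a log2 fold change of at least 1 and 496 at an adjusted p of 0.01; 1436 to 2516 were called with 1 library left out. The splits into higher and lower were 985 and 1181 with upper-quartile factors, and 869 and 1133 without a filter. No sign of pairing by replicate number was seen, though these values cannot exclude it. Same-numbered libraries correlated from -0.34 to 0.35 in their deviations, 1 of 7 pairs above 0.1, and 1 of 7 lymphoma libraries correlated best with its own number. Of the 24 genes taken by rule, 9 were called in the 5-digit libraries, 1 with the scaffold covariate, and 20 to 23 with 1 library left out. Those called in the 5-digit libraries were all rises. The falls kept their direction there but none was called (edgeR adjusted p from 0.0617 to 0.588). Without single-exon and scaffold genes 13 were called, which were all of the 24 that this run kept for testing. Over single genes and alternatives, direction and call were kept 661 times and direction alone 89 times. With the scaffold covariate 3 reversed, the 1869-base scaffold gene (-0.07), the chromosome 1 gene starting at 60597757 (-3.42) and the chromosome 27 gene starting at 37777489 (1.71). The 16 chromosomes became 7 with camera's preset correlation, 0 with an estimated one, 5 with medians (4 of the 16), 7 without the density trend, 9 without lymphoma replicates 2 and 7, 0 in the 5-digit libraries, where all 16 kept their direction but the smallest exact p, 0.0278, leaves little room for a pass, and 14 to 19 with 1 library left out. The larger lymphoma spread, 11.8, lost its call over all tested genes (19.6), with Spearman distance (0.00405) and in 10 of 14 runs with 1 library left out (9.13 to 13.7 in these 10, up to 15.8 over all 14). Separation of the groups was called throughout (pseudo-F 5.14 to 6.43 with 1 library left out), as was the short-gene share (log2 difference 2.78 to 3.38), except that it was 0.46 without the 3 chromosome 8 genes. The scaffold share differed by 7.46 to 8.30, but its genes were chosen for that difference in the same libraries. The 3 chromosome 8 genes were chosen in the same way. The 3 regions were called in all 14 runs with 1 library left out. Apart from subsets of libraries or genes and stricter thresholds, the cause was not tested. Neutrophil and erythroid covariates, TMM without the erythroid list, distances without it, and all alternatives of the gene lists were not run, since no list could be matched. At the depth of these libraries, simulated changes of a log2 fold of 1 were recovered in 43.0% of tested cases and of 2 in 75.5%. Only 200 genes were changed there, far fewer than the 2132 called in the data, so recovery in the data may differ. The simulation did not test depth as the cause, and thinning all libraries to the smallest total left 2081 calls.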

Other observations

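Ratios between abundant genes differed between the groups, in comparisons chosen after the data were seen. The chromosome 21 gene at 28178124 to 28206005 spans a 3-exon gene at 28181549 to 28182932. The first had 70.3 ± 36.4 counts per count of the second in lymphoma and 7.32 ± 2.28 in non-lymphoma libraries (SD, n = 7 each; exact permutation p = 0.000583, the smallest possible, adjusted p = 0.00219 over 15 measures). Within the 5-digit libraries the fold was 10.5 (exact permutation p = 0.0278). The contained gene itself had a log2 fold change of -1.03 (SE 0.52, edgeR adjusted p = 0.173), and of -1.72 without lymphoma replicate 2 (edgeR adjusted p = 0.023). The ratio of the chromosome 21 gene to the abundant chromosome 6 gene was 2.88 ± 3.28 in lymphoma and 0.503 ± 0.117 in non-lymphoma libraries (SD, n = 7 each; exact permutation p = 0.000583), or 1.67 ± 0.73 (SD, n = 6) in lymphoma without replicate 2, which had 10.2, and every lymphoma library lay above every non-lymphoma library. Overlapping genes counted without strand share this uncertainty, and the values are given without an explanation.

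Among the placed short single-exon genes, several outside chromosome 8 rose by large folds at low levels. The gene of 238 bases on chromosome 24 starting at 5091561 had a log2 fold change of 5.04 (SE 0.39, edgeR adjusted p = 4.93e-06), at 0.0231 ± 0.0107% of counts in lymphoma and 0.000804 ± 0.000362% in non-lymphoma libraries (SD, n = 7 each). On chromosome X, the genes starting at 47858801 and 89603324 had log2 fold changes of 6.68 and 5.19 (SE 0.61 and 0.52, edgeR adjusted p = 3.19e-05 and 6.89e-05).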
